A study of Caenorhabditis elegans with 12 samples.

How the data were processed

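The data are 12 polyA-selected, paired-end mRNA libraries of whole animals, 4 each of N2, of strain MGH558 (labelled full-length NPP-16 overexpression) and of strain MGH721 (labelled ΔIDR overexpression). Animals were synchronised by bleaching, grown at 20 °C on Escherichia coli and collected on adult day 1. Per the labels' protocols about 20 M reads of 150 bp, paired-end, were obtained per sample, in independent replicate experiments. Groups and replicate numbers were taken from the labels.

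Per the submitters' processing notes, the tools were FastQC 0.11.8, MultiQC 1.19, Salmon 1.9.0, R 4.3.2 and DESeq2 1.42.1, with the builds WBcel235 and ce11. Strand setting, Salmon's library type and bias options, and the way transcripts were summed to genes are not given in the sources used here. The deposited gene table holds estimated counts (expected counts that need not be whole; 30.3% of values were not), with no normalization by the authors. Deposited files for each library hold, per the file headers, estimated counts, TPM and effective lengths for 35749 transcripts. Summed by gene, the deposited estimated counts of the transcripts equalled the gene table within 0.01 for 99.98% of values, and 6 genes differed. The authors deposited TPM values (a share of each library, scaled by Salmon for effective length), which served for length scaling alone. The deposited sample sheet gives RNA concentration in ng/µl and the absorbance ratios A260/A280 and A260/A230, measured on a spectrophotometer per the labels.

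Effective lengths also describe the libraries. Among 3620 transcripts longer than 3000 nt, the most common difference between length and effective length was 213 to 225 nt in N2, 212 to 227 nt in the labelled full-length libraries and 213 to 221 nt in the labelled ΔIDR libraries. The median difference was 315 ± 23.4, 225 ± 10.9 and 224 ± 10.9 nt (SD, n = 4), with an exact two-sided permutation p of 0.0286 for either line against N2 (0.0857 after Benjamini-Hochberg adjustment over 6 comparisons). In 3.07% to 6.48% of transcripts the effective length exceeded the length, so these values hold more than a mean fragment length.

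Estimated counts were rounded to whole numbers. The table has 21982 genes, 20098 protein coding and 1884 pseudogenes, and names each gene; 21896 matched the WBcel235 annotation of Ensembl release 115, from which coordinates were taken. The annotation carries the build named in the submitters' notes. Genes were filtered with filterByExpr (14696 kept), scaled with TMM, and tested with edgeR 4.0.16's quasi-likelihood F test with all 12 libraries in one fit and no covariate, in R 4.3.3. Benjamini-Hochberg adjustment ran over the genes tested, and genes with an adjusted p under 0.05 are called higher or lower. SEs are those of the log2 fold change. CPM uses TMM-scaled totals. Because strand is not given, reads of overlapping genes on opposite strands cannot be told apart, and near-identical copies share reads.

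The 37 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) and, as alternatives, with camera's estimated correlation and with fry, adjusted over the 37 lists. Of these lists the V-ATPase, fatty acid oxidation, fatty acid synthesis, longevity, DAF-16, lysozyme and intestine lists share members with another list. Lists, tests, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule took npp-16 and 7 regulators (hlh-30, lipl-1, lipl-3, lgg-1, sqst-1, lmp-1 and fat-7) in each comparison. It added the 8 higher and 8 lower genes with the largest change among called genes with a mean of at least 5 CPM and no overlap between groups. From each list past camera, or with at least 5 called members, it took up to 2 higher and 2 lower members with the smallest adjusted p. It named 159, 159 and 107 genes. The text prints 45, 36 and 39 of them, picked after their values were seen, and the alternatives were computed for these.

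Alternatives chosen before the data were seen were DESeq2's size factors, DESeq2 1.42.0's Wald test, no filter, a filter of 5 CPM in 4 libraries, the 8 libraries of a comparison alone, a fit with the replicate number as a block, a fold limit, gene totals from the library files, and leaving out each library in turn. Added after seeing the data were scaling by total counts, voom with sample weights per group, length-scaled counts, N2 replicates 3 and 4 as the only controls, families of genes that share a symbol prefix, and removal of the length trend. For the last, the deviation of log2 CPM from the gene's mean was smoothed on log2 transcript length in each library (lowess, span 0.3) and subtracted as an offset. Length-matched medians come from 10000 random lists drawn from 50 length pools. GC content was not tested, since no sequence was used here. RNA extract values and npp-16 were compared with exact two-sided permutation tests.

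Depth was 20.2 to 27.6 M estimated counts per library. On simulated counts for the real genes, the pipeline (13985 genes tested) recovered 23.4%, 75.0% and 95.3% of genes changed 1.5-, 2- and 4-fold for the labelled full-length libraries against N2, and 23.4%, 81.2% and 96.9% for the comparison of the lines. Of 13772 unchanged genes, 10 and 11 were called. A V-ATPase list changed 1.5-fold was called in both, and no other list. No pair of libraries was identical.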

Results

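Polyadenylated RNA from whole Caenorhabditis elegans on adult day 1 was sequenced in 12 libraries, 4 for each of 3 genotypes. N2, the Bristol laboratory wild type, was the control. Strain MGH558 carries an integrated transgene labelled as overexpressing full-length NPP-16, the worm counterpart of the nucleoporin NUP50, a nuclear pore protein that also works in import. Strain MGH721 carries a transgene labelled as overexpressing NPP-16 without its intrinsically disordered region (ΔIDR), amino acids 245 to 354 of 497. Per the labels the replicates were independent experiments. Estimated counts summed to 24.6, 20.8, 21.3 and 21.4 M in N2 replicates 1 to 4. They summed to 23.3, 22.1, 21.8 and 22.4 M in the labelled full-length libraries, and to 27.6, 20.2, 22.5 and 21.97 M in the labelled ΔIDR libraries. Of 21982 genes, 14696 had enough counts to be tested.

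The lines are labelled as overexpressing NPP-16, yet npp-16 counts were lower in both than in N2. The gene (WBGene00003802) lies on chromosome III at 11915928 to 11917873 on the plus strand in WBcel235 and has 4 exons. Its mean level was 124 ± 49.7 CPM in N2 (SD, n = 4), 50.95 ± 3.69 CPM in the labelled full-length libraries and 37.3 ± 1.85 CPM in the labelled ΔIDR libraries. Each library of either line lay below all 4 N2 libraries, which held 172, 162, 90.6 and 73.4 CPM. Against N2 the difference was log2 fold change -1.29, SE 0.215, edgeR adjusted p = 8.46e-05 for the labelled full-length libraries and log2 fold change -1.74, SE 0.218, edgeR adjusted p = 6.14e-06 for the labelled ΔIDR libraries. With only N2 replicates 3 and 4 as controls the values were -0.69 and -1.14, and with total counts the first was -0.78. Between the lines it was log2 fold change 0.45, SE 0.213, edgeR adjusted p = 0.143, which did not pass, although the labelled full-length libraries all lay above the labelled ΔIDR ones. The exact two-sided permutation test of CPM gave p = 0.0286 for each of the 3 comparisons (0.0286 after Benjamini-Hochberg adjustment), the smallest value that 4 against 4 can give. The sources used here do not give the transgenes' sequence, promoter or 3′ UTR, so how much transgene RNA these estimated counts hold, and whether they can check the labels, is not known. Directions below are therefore given for the libraries as labelled, not for more or less NPP-16.

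**Figure D1:**
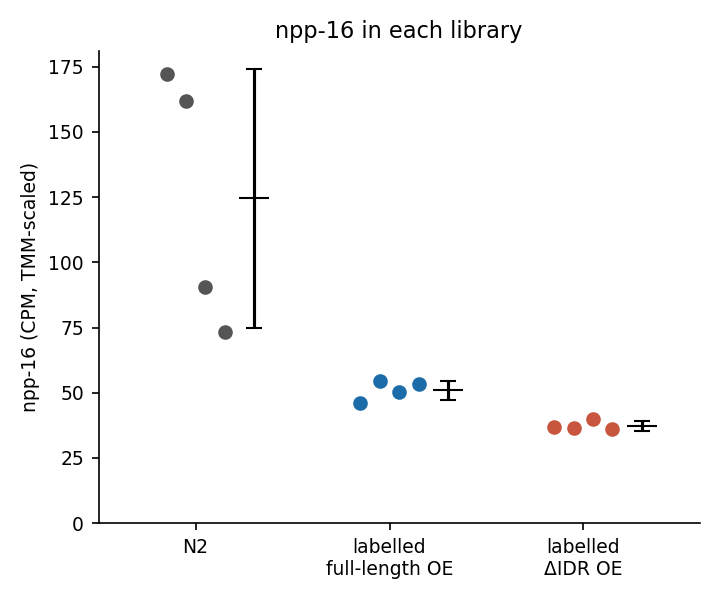
Level of npp-16 in each library in CPM scaled by TMM, for N2 and the 2 lines labelled as overexpressing (OE). Points are libraries, horizontal bars with whiskers are the mean and SD of 4 libraries, and each library of both lines lies below the lowest N2 library at 73.4 CPM.

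The 3 groups lay apart in a principal component analysis of log2 CPM, and the N2 libraries were the most spread. The first component held 63.1% of the variance and placed N2 replicates 1 to 4 at -106, -93.1, -67.3 and -50.9, the labelled full-length libraries at 16.5 to 27.6 and the labelled ΔIDR libraries at 45.4 to 64.1. The median SD of log2 CPM across genes was 0.29 in N2, 0.15 in the labelled full-length libraries and 0.18 in the labelled ΔIDR libraries. The deposited RNA concentrations averaged 341 ± 130.4 ng/µl in N2 (SD, n = 4), 86.0 ± 10.6 ng/µl in the labelled full-length line and 92.96 ± 26.2 ng/µl in the labelled ΔIDR line. The lowest N2 extract held 197 ng/µl and the highest extract of a line 129.9 ng/µl. The exact two-sided permutation p was 0.0286 for either line against N2 and 0.800 between the lines (0.0643, 0.0643 and 0.800 after Benjamini-Hochberg adjustment over 9 comparisons of 3 extract measures). The A260/A280 ratio averaged 2.04 ± 0.0131, 1.97 ± 0.0159 and 1.96 ± 0.0226 in the same order, with an exact permutation p of 0.0286 for either line against N2 (0.0643 adjusted).

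**Figure D2:**
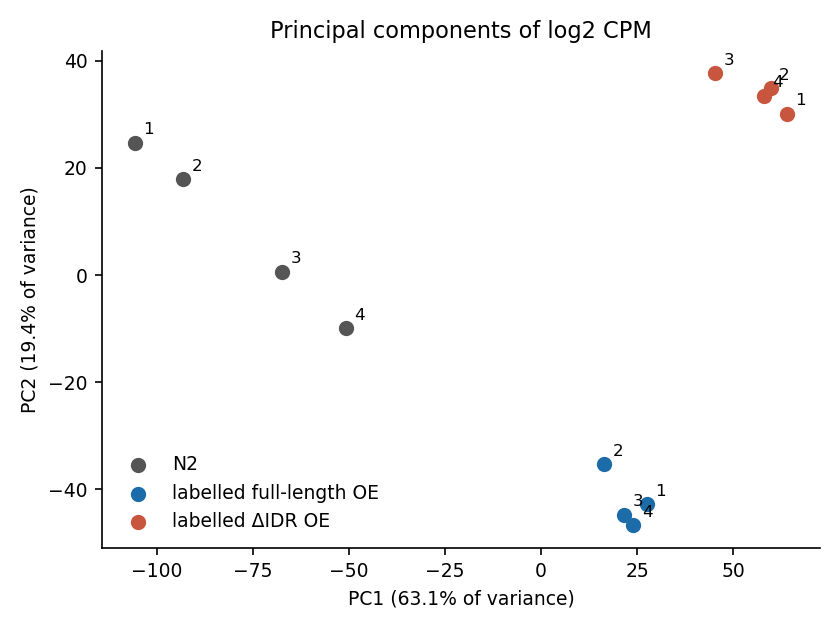
First 2 principal components of log2 CPM over the tested genes, with each library marked by its replicate number. The groups are N2 and the 2 lines labelled as overexpressing (OE); on the first component N2 spans -106 to -50.9 and the lines lie above 16.

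Fold changes against N2 followed transcript length. Among the shortest eighth of genes (81 to 582 nt) the median log2 fold change was 0.70 in the labelled full-length libraries and 0.69 in the labelled ΔIDR libraries, and among the longest eighth (2565 to 45876 nt) it was -1.16 and -1.13. Spearman's rho of fold change with length was -0.539 and -0.452 across 14695 genes, and -0.0309 between the lines; genes are not independent replicates. The 82 cytosolic ribosomal protein genes alone gave -0.570, -0.560 and -0.122. By library, the median deviation of the shortest eighth minus that of the longest was -1.84, -1.43, -0.86 and -0.54 in N2 replicates 1 to 4, 0.45 to 0.70 in the labelled full-length libraries and 0.24 to 0.77 in the labelled ΔIDR libraries. In the text below, a length-matched median is the median fold change of random genes of the same lengths as a list.

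**Figure D3:**
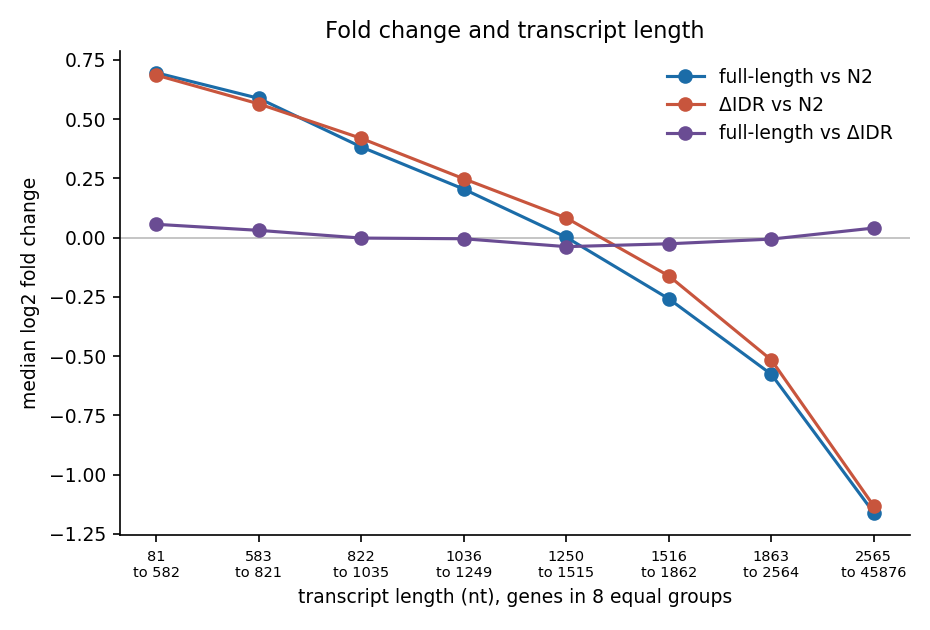
Median log2 fold change of genes sorted by transcript length (nt) into 8 groups of nearly equal size, for the 3 comparisons of libraries as labelled. Both comparisons with N2 run from about 0.70 for the shortest to below -1.13 for the longest transcripts, while the comparison of the lines stays between -0.04 and 0.06.

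The comparison of the labelled full-length libraries with N2 asks which transcripts differ with that transgene, although npp-16 itself was lower there. Genes of the germline, of yolk and of the nuclear pore were lower in the labelled full-length libraries, and genes for neuropeptides and for the response to intracellular pathogens were higher. With an estimated correlation between genes instead of camera's preset one, none of the 20 lists that passed did so, with adjusted p from 0.259 to 0.645. The yolk protein gene vit-1 was at 821 ± 151 CPM against 4231 ± 1692 CPM in N2 (SD, n = 4), and pgl-1, which encodes a protein of germline P granules, at 208 ± 11.3 CPM against 669 ± 188 CPM. In the other direction ins-7, which encodes an insulin-like peptide, was at 18.96 ± 1.76 CPM against 1.62 ± 0.323 CPM, and fbxa-24, which encodes an F-box protein, at 27.1 ± 2.20 CPM against 1.51 ± 0.191 CPM. C08F11.7, among the genes with the largest increases, was at 4.26 (SE 0.148). By edgeR's quasi-likelihood test, 4846 genes were higher and 5238 lower at an adjusted p under 0.05, and 20 of 37 gene lists passed camera, the test of a list against all other genes.

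Germline genes made up the list with the lowest median. Of this list, 35 of 38 oocyte and germline genes were lower, 1 was higher and 2 did not pass (35 and 1 adjusted over the list alone). Its median log2 fold change was -1.78, against a length-matched median of -0.43 (adjusted p = 0.515 with an estimated correlation). Examples are pgl-1 at -1.68 (SE 0.162), the P granule helicase gene glh-1 at -1.54 (SE 0.159), and the eggshell proteoglycan gene cpg-1 at -2.64 (SE 0.372). The oocyte regulator lin-41, among the genes with the largest decrease, was at -2.79 (SE 0.385). All 6 vitellogenin genes were lower (6 adjusted over the list alone), with vit-3 at -1.99 (SE 0.254), a median of -1.49 and a length-matched median of -1.23 (adjusted p = 0.543 with an estimated correlation). For sperm, 47 of 70 genes were lower, 2 were higher and 21 did not pass (47 and 2 adjusted over the list alone), among them the phosphatase gene gsp-4 at -1.63 (SE 0.154) and the major sperm protein gene msp-113 at -1.37 (SE 0.130). Their median was -1.09 while length-matched genes had 0.57 (adjusted p = 0.543 with an estimated correlation). The msp and vit genes include near-identical copies whose reads Salmon divides, so single members are uncertain. For the small RNA pathways, 35 of 47 genes were lower, 5 were higher and 7 did not pass (35 and 5 adjusted over the list alone), with the Argonaute gene csr-1 at -1.42 (SE 0.148) and the exonuclease gene mut-7 at -1.66 (SE 0.172). Median and length-matched median were -1.07 and -0.81 (adjusted p = 0.543 with an estimated correlation). Without the length trend, the vitellogenin and small RNA lists no longer passed camera (adjusted p = 0.429 and 0.392).

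Further lists were lower as well. Among nucleoporins, importins and the Ran system, npp-16 left out, 34 of 39 genes were lower, 2 were higher and 3 did not pass (34 and 2 adjusted over the list alone), with the pore membrane protein gene npp-12 at -1.56 (SE 0.150) and npp-14 at -1.58 (SE 0.156). The median was -1.58 against -0.71 for length-matched genes (adjusted p = 0.515 with an estimated correlation). In the cytosolic ribosome, 63 of 82 protein genes were lower, 12 were higher and 7 did not pass (63 and 12 adjusted over the list alone), such as rpl-28 at -1.32 (SE 0.122) and rpl-19 at -1.23 (SE 0.116). The list's median of -0.95 lay opposite to a length-matched median of 0.62 (adjusted p = 0.515 with an estimated correlation). The short ribosomal genes rpl-41.1 at 0.87 (SE 0.141) and rpl-39 at 0.73 (SE 0.141) were higher, and neither call held without the length trend (0.20 with adjusted p = 0.0690, and 0.00 with adjusted p = 0.983). In the proteasome, 23 of 33 subunit genes were lower, 4 were higher and 6 did not pass (23 and 4 adjusted over the list alone), with rpt-1 at -1.53 (SE 0.151), rpn-7 at -1.38 (SE 0.133), a median of -0.95 and a length-matched median of 0.10 (adjusted p = 0.515 with an estimated correlation). For the endoplasmic reticulum stress response, 17 of 18 genes were lower and 1 did not pass (17 adjusted over the list alone), with the protein disulphide isomerase gene pdi-1 at -1.59 (SE 0.192) and medians of -0.96 and -0.54 length-matched (adjusted p = 0.554 with an estimated correlation). Without the length trend this list did not pass camera (adjusted p = 0.0631). For the nuclear-encoded respiratory chain, 30 of 44 genes were lower, 10 were higher and 4 did not pass (30 and 10 adjusted over the list alone), with medians of -0.74 and 0.30 length-matched (adjusted p = 0.515 with an estimated correlation). All 12 protein-coding genes of mitochondrial DNA were higher (12 adjusted over the list alone), among them atp-6 at 1.17 (SE 0.132) and ctc-2 at 1.06 (SE 0.132), with medians of 0.98 and 0.39 length-matched (adjusted p = 0.515 with an estimated correlation).

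Among cuticle collagens, 53 of 127 genes were lower, 6 were higher and 68 did not pass (53 and 6 adjusted over the list alone), with col-149 at -3.29 (SE 0.190) and col-142 at -2.003 (SE 0.105). Their median of -0.59 compared with 0.25 for length-matched genes (adjusted p = 0.543 with an estimated correlation). In the list of longevity and nutrient signalling genes, 22 of 34 genes were lower, 4 were higher and 8 did not pass (22 and 4 adjusted over the list alone), with medians of -0.77 and -0.46 length-matched (adjusted p = 0.645 with an estimated correlation). It did not pass camera without the length trend (adjusted p = 0.315). For the vacuolar proton pump, which acidifies lysosomes, 15 of 21 genes were lower, 4 were higher and 2 did not pass (15 and 4 adjusted over the list alone), with the B subunit gene vha-12 at -1.02 (SE 0.104). The pump list's median was -0.40 (-0.10 length-matched; adjusted p = 0.515 with an estimated correlation) but 0.05 when libraries were scaled by total counts, where the list did not pass (adjusted p = 0.360). With DESeq2's size factors it did not pass either (adjusted p = 0.0591), nor without N2 replicate 3 or 4 (0.0548 and 0.104) or with the replicate number as a block (0.0641).

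Intracellular pathogen response and neuropeptide genes had the highest medians of all lists. Among neuropeptide and insulin-like peptide genes, 92 of 117 genes were higher, 5 were lower and 20 did not pass (94 and 5 adjusted over the list alone), with nlp-51 at 2.96 (SE 0.203) and ins-7 at 3.54 (SE 0.154). The median was 1.02 against 0.65 for length-matched genes (adjusted p = 0.515 with an estimated correlation). For the intracellular pathogen response, genes raised by microsporidia and viruses, 25 of 28 genes were higher and 3 did not pass (25 adjusted over the list alone), with pals-32 at 2.64 (SE 0.254), the ubiquitin ligase component gene skr-5 at 2.42 (SE 0.208), a median of 1.09 and a length-matched median of 0.23 (adjusted p = 0.259 with an estimated correlation). For lysozymes and antimicrobial peptides, 30 of 71 genes were higher, 3 were lower and 38 did not pass (27 and 2 adjusted over the list alone), with the saposin-like gene spp-2 at 2.39 (SE 0.136) and the lysozyme gene lys-6 at 2.301 (SE 0.135). Their median of 0.41 lay below the length-matched 0.66 (adjusted p = 0.515 with an estimated correlation), and it turned to -0.18 with the length trend removed (camera adjusted p = 0.918). In the C-type lectin family, 41 of 106 genes were higher, 25 were lower and 40 did not pass (40 and 25 adjusted over the list alone). Its median and length-matched median were both 0.15 (adjusted p = 0.515 with an estimated correlation). This last call ended with the length trend removed (adjusted p = 0.171), with DESeq2's size factors (0.0587), with total counts (0.0556), and without N2 replicate 3 (0.0639) or the labelled full-length replicate 4 (0.0540).

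Further metabolic lists were higher on balance. For targets of the FOXO factor DAF-16, 11 of 21 genes were higher, 3 were lower and 7 did not pass (11 and 3 adjusted over the list alone), with the alcohol dehydrogenase gene sodh-1 at 3.18 (SE 0.208) and, in the other direction, the small heat shock protein gene sip-1 at -1.88 (SE 0.246). Medians were 0.76 and 0.30 length-matched (adjusted p = 0.515 with an estimated correlation), and the list did not pass camera without the length trend (adjusted p = 0.0526). Among glucuronosyltransferases, which conjugate foreign compounds, 31 of 58 genes were higher, 12 were lower and 15 did not pass (32 and 12 adjusted over the list alone), with ugt-17 at 1.201 (SE 0.107) and medians of 0.40 and -0.26 length-matched (adjusted p = 0.515 with an estimated correlation). For lipases, 9 of 20 genes were higher, 2 were lower and 9 did not pass (9 and 2 adjusted over the list alone), with medians of 0.46 and 0.07 length-matched (adjusted p = 0.515 with an estimated correlation). The lysosomal lipase genes lipl-3 and lipl-4 were higher at 3.68 (SE 0.232) and 2.35 (SE 0.225), and the fat-droplet lipase gene atgl-1 was lower at -1.37 (SE 0.202). The lipase list did not pass with total counts (adjusted p = 0.0521) or without N2 replicate 4 (0.0785). Another lysosomal lipase gene, lipl-1, was at 1.08 (SE 0.394, edgeR adjusted p = 0.0241), a call lost without the labelled full-length replicate 4 (0.79, adjusted p = 0.1).

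Autophagy and lysosome genes went both ways. The autophagosome protein gene lgg-1 was at 1.07 (SE 0.110, edgeR adjusted p = 2.92e-06), whereas hlh-30, which encodes the TFEB-like regulator of lysosome genes, was at -0.47 (SE 0.141, edgeR adjusted p = 0.00824) and the lysosome membrane gene lmp-1 at -0.79 (SE 0.147, edgeR adjusted p = 2.09e-04). The hlh-30 difference turned to 0.33 with the length trend removed (adjusted p = 0.00373), to 0.00 with total counts (0.993), and did not pass with only N2 replicates 3 and 4 as controls (-0.17, adjusted p = 0.208). The cargo receptor gene sqst-1 was at -0.05 (SE 0.124, edgeR adjusted p = 0.721); its sign turned with the length trend removed (0.68, adjusted p = 6.52e-05). The desaturase gene fat-7 was at 0.31 (SE 0.257, edgeR adjusted p = 0.293) and passed with total counts (0.73, adjusted p = 0.0214). The autophagy list had 7 higher and 15 lower of 26 (median -0.37, camera adjusted p = 0.513, 7 higher and 16 lower adjusted over the list alone). The lysosome list had 18 higher and 28 lower of 56 (median -0.34, camera adjusted p = 0.658). The fatty acid oxidation list had 13 higher and 22 lower of 43 (median -0.34, camera adjusted p = 0.402). None of these 3 passed camera.

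The other lists did not pass camera. Cytochrome P450 genes had 29 higher and 12 lower of 62 (median 0.30, camera adjusted p = 0.0596). Glutathione S-transferase genes had 17 higher and 5 lower of 42 (median 0.28, camera adjusted p = 0.236, 16 higher and 5 lower adjusted over the list alone). The p38 immune targets had 6 higher and 10 lower of 22 (median -0.31, camera adjusted p = 0.958). Fatty acid synthesis genes had 6 higher and 10 lower of 24 (median 0.11, camera adjusted p = 0.854). Hypodermis and moulting genes had 2 higher and 14 lower of 33 (median -0.41, camera adjusted p = 0.131, 2 higher and 13 lower adjusted over the list alone). Body wall muscle had 2 higher and 11 lower of 23 (median -0.24, camera adjusted p = 0.183, 1 higher and 11 lower adjusted over the list alone). Pharynx had 6 higher and 5 lower of 14 (median 0.11, camera adjusted p = 0.748). Intestine had 4 higher and 13 lower of 20 (median -0.59, camera adjusted p = 0.236, 5 higher and 13 lower adjusted over the list alone). Neurons had 5 higher and 6 lower of 20 (median -0.03, camera adjusted p = 0.864). Early embryo genes had 11 higher and 3 lower of 35 (median 0.24, camera adjusted p = 0.241, 7 higher and 1 lower adjusted over the list alone). Cytosolic chaperones had 2 higher and 9 lower of 20 (median -0.17, camera adjusted p = 0.241). The mitochondrial unfolded protein response had 3 higher and 6 lower of 12 (median -0.46, camera adjusted p = 0.241). Mitochondrial ribosomal proteins had 33 higher and 21 lower of 67 (median 0.24, camera adjusted p = 0.318). Histones had 8 higher and 15 lower of 46 (median -0.26, camera adjusted p = 0.714). Adjusted over the list alone, the counts of these lists were the same where none is given. The P450 list passed with the length trend removed, with total counts, with only N2 replicates 3 and 4, and without N2 replicate 1 or 2 (adjusted p from 0.00104 to 0.0450). Histones passed, as lower, with the length trend removed (adjusted p = 0.00111), as did mitochondrial ribosomal proteins with the direction turned (0.0330), and body wall muscle passed with only N2 replicates 3 and 4 as controls (0.0390). Scaling by total counts moved the median of all genes by 0.44 in this comparison, and under it the medians of autophagy, body wall muscle, cytosolic heat shock response, fatty acid oxidation, histones, hypodermis and moulting, lysosome, neurons and p38 immune targets turned above 0. With the length trend removed the medians of autophagy, body wall muscle, intestine, lysosome and neurons turned above 0 and those of glutathione S-transferases and mitochondrial ribosomal proteins below 0, and with only N2 replicates 3 and 4 as controls that of neurons turned above 0.

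Scaling decides how the calls divide. The share of called genes that were higher was 48.1% with TMM and 67.1% with total counts; 8364 of the 10084 genes called were called with total counts as well, 8510 with only N2 replicates 3 and 4 as controls and 7312 with the length trend removed.

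The comparison of the labelled ΔIDR libraries with N2 asks the same of the transgene without the disordered region. Immune effector genes were among the largest increases, and germline genes among the largest decreases. The infection response gene irg-5 was at 683 ± 38.2 CPM in the labelled ΔIDR libraries against 6.06 ± 1.84 CPM in N2 (SD, n = 4), T24B8.5, a target of the p38 kinase PMK-1, at 65.6 ± 12.18 CPM against 1.62 ± 0.247 CPM, and the C-type lectin gene clec-13 at 26.99 ± 2.15 CPM against 0.0522 ± 0.0607 CPM. The oocyte yolk receptor gene rme-2 was at 95.1 ± 23.96 CPM against 1021 ± 562 CPM. By edgeR's quasi-likelihood test 5523 genes were higher and 5053 lower, and 18 of 37 lists passed camera. With an estimated correlation the adjusted p of these 18 lists ran from 0.267 to 0.775.

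Immune lists were higher. The list named p38 immune targets had 13 higher, 5 lower and 4 uncalled of 22 (14 and 5 adjusted over the list alone). Up were irg-5 at 6.82 (SE 0.211) and T24B8.5 at 5.35 (SE 0.182). Down were dod-24 at -2.81 (SE 0.188) and atf-7, a pathway gene rather than a target, at -1.15 (SE 0.144). The list's median was 0.69, with 0.10 for length-matched genes (adjusted p = 0.390 with an estimated correlation). Of lysozymes and antimicrobial peptides, 44 of 71 genes were higher, 10 were lower and 17 did not pass (44 and 10 adjusted over the list alone), with lys-10 at 6.14 (SE 0.230), lys-6 at 4.64 (SE 0.145) and medians of 0.91 and 0.65 length-matched (adjusted p = 0.423 with an estimated correlation). Of C-type lectins, 49 of 106 genes were higher, 27 were lower and 30 did not pass (49 and 27 adjusted over the list alone), with clec-5 at 3.46 (SE 0.0997) and medians of 0.45 and 0.20 length-matched (adjusted p = 0.423 with an estimated correlation). For the intracellular pathogen response, 27 of 28 genes were higher and 1 did not pass (27 adjusted over the list alone), with pals-6 at 4.995 (SE 0.192) and medians of 1.31 and 0.27 length-matched (adjusted p = 0.267 with an estimated correlation).

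Detoxification and neuropeptide lists were higher too. For cytochrome P450 enzymes, 31 of 62 genes were higher, 13 were lower and 18 did not pass (32 and 13 adjusted over the list alone), with cyp-13A5 at 4.35 (SE 0.136) and medians of 0.53 and -0.11 length-matched (adjusted p = 0.350 with an estimated correlation). For glutathione S-transferases, 23 of 42 genes were higher, 4 were lower and 15 did not pass (23 and 4 adjusted over the list alone), with gst-39 at 3.93 (SE 0.137). Their median of 0.49 was close to the length-matched 0.51 (adjusted p = 0.539 with an estimated correlation), and the list did not pass camera without the length trend (adjusted p = 0.438). For glucuronosyltransferases, 30 of 58 genes were higher, 9 were lower and 19 did not pass (30 and 9 adjusted over the list alone), with ugt-7 at 2.53 (SE 0.135) and medians of 0.34 and -0.19 length-matched (adjusted p = 0.539 with an estimated correlation). Among neuropeptides, 96 of 117 genes were higher, 4 were lower and 17 did not pass (97 and 4 adjusted over the list alone), with nlp-61 at 3.37 (SE 0.155) and medians of 1.096 and 0.64 length-matched (adjusted p = 0.423 with an estimated correlation). All 12 mitochondrial DNA genes were higher (12 adjusted over the list alone), with atp-6 at 0.99 (SE 0.131) and medians of 0.80 and 0.40 length-matched (adjusted p = 0.574 with an estimated correlation). That list did not pass camera without the length trend (adjusted p = 0.0813).

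Germline lists were lower. For oocyte and germline genes, 34 of 38 genes were lower, 1 was higher and 3 did not pass (34 and 1 adjusted over the list alone), with rme-2 at -3.42 (SE 0.336), the eggshell gene cbd-1 at -3.44 (SE 0.370), cpg-1 at -3.46 (SE 0.385), lin-41 at -3.88 (SE 0.406) outside the list, and pgl-1 at -1.99 (SE 0.163). The median was -2.03 against -0.33 for length-matched genes (adjusted p = 0.539 with an estimated correlation). For sperm, 58 of 70 genes were lower and 12 did not pass (59 adjusted over the list alone), with gsp-4 at -2.16 (SE 0.159), msp-113 at -1.76 (SE 0.132) and medians of -1.40 and 0.56 length-matched (adjusted p = 0.539 with an estimated correlation). All 6 vitellogenin genes were lower (6 adjusted over the list alone), with vit-1 at -2.91 (SE 0.252) and medians of -2.23 and -1.199 length-matched (adjusted p = 0.539 with an estimated correlation). For the small RNA pathways, 37 of 47 genes were lower, 7 were higher and 3 did not pass (37 and 7 adjusted over the list alone), with the germline Argonaute gene hrde-1 at -2.62 (SE 0.241) and medians of -1.08 and -0.71 length-matched (adjusted p = 0.539 with an estimated correlation). The small RNA list did not pass camera without the length trend (adjusted p = 0.0813). Among nuclear pore and transport genes, 36 of 39 genes were lower and 3 were higher (36 and 3 adjusted over the list alone), with npp-12 at -1.65 (SE 0.150) and medians of -1.68 and -0.61 length-matched (adjusted p = 0.539 with an estimated correlation). In the proteasome, 23 of 33 genes were lower, 2 were higher and 8 did not pass (23 and 2 adjusted over the list alone), with rpt-1 at -1.57 (SE 0.151) and medians of -0.94 and 0.14 length-matched (adjusted p = 0.539 with an estimated correlation). In the cytosolic ribosome, 56 of 82 genes were lower, 10 were higher and 16 did not pass (56 and 10 adjusted over the list alone), with rpl-28 at -1.07 (SE 0.121) and medians of -0.51 and 0.61 length-matched (adjusted p = 0.574 with an estimated correlation).

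Cuticle collagens divided: 69 of 127 genes were lower, 26 were higher and 32 did not pass (69 and 26 adjusted over the list alone), with col-149 at -3.34 (SE 0.190) and col-95 at 3.102 (SE 0.117). Their median was -0.82 and the length-matched one 0.30 (adjusted p = 0.775 with an estimated correlation), and the call ended without N2 replicate 1 (adjusted p = 0.0645) or 4 (0.176). In longevity and nutrient signalling, 19 of 34 genes were lower, 5 were higher and 10 did not pass (19 and 5 adjusted over the list alone), with medians of -0.46 and -0.38 length-matched (adjusted p = 0.775 with an estimated correlation). Its camera adjusted p of 0.0485 was above 0.05 in 9 alternatives besides the estimated correlation, with values from 0.0513 to 0.438, among them the replicate number as a block (0.0550) and leaving out N2 replicate 1 or 2 or the labelled ΔIDR replicate 1 or 2. Among the 7 regulators of autophagy, lysosomes and fat named in advance, lgg-1 was higher at 1.194 (SE 0.110, edgeR adjusted p = 5.79e-07), sqst-1 at 0.92 (SE 0.124, edgeR adjusted p = 1.09e-05), lipl-1 lower at -1.91 (SE 0.473, edgeR adjusted p = 0.00216) and lipl-3 lower at -1.16 (SE 0.344, edgeR adjusted p = 0.00703). Both lipases had few labelled ΔIDR counts outside replicate 4, without which lipl-1 stood at -2.84 (adjusted p = 4.01e-05). The lipl-3 call ended without N2 replicate 4 (-0.82, adjusted p = 0.0951) and with total counts (-0.82, 0.0634). Values for hlh-30, lmp-1 and fat-7 were -0.06 (SE 0.140, edgeR adjusted p = 0.703), -0.21 (SE 0.146, edgeR adjusted p = 0.205) and -0.11 (SE 0.257, edgeR adjusted p = 0.717). With the length trend removed hlh-30 stood at 0.70 (adjusted p = 4.14e-06) and lmp-1 at -0.45 (adjusted p = 0.0148), and without N2 replicate 4 lmp-1 stood at -0.33 (adjusted p = 0.0225).

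The other lists of this comparison did not pass camera. Autophagy had 9 higher and 11 lower of 26 (median -0.01, camera adjusted p = 0.981). Lysosome had 15 higher and 26 lower of 56 (median -0.25, camera adjusted p = 0.448). The vacuolar proton pump had 12 higher and 3 lower of 21 (median 0.21, camera adjusted p = 0.431). Lipases had 8 higher and 8 lower of 20 (median 0.15, camera adjusted p = 0.967). Fatty acid oxidation had 15 higher and 20 lower of 43 (median -0.19, camera adjusted p = 0.751, 15 higher and 21 lower adjusted over the list alone). Fatty acid synthesis had 3 higher and 13 lower of 24 (median -0.49, camera adjusted p = 0.0652, 2 higher and 12 lower adjusted over the list alone). Endoplasmic reticulum stress genes had 1 higher and 12 lower of 18 (median -0.57, camera adjusted p = 0.0561). Mitochondrial stress genes had 3 higher and 7 lower of 12 (median -0.57, camera adjusted p = 0.317). Cytosolic chaperones had 8 higher and 8 lower of 20 (median 0.25, camera adjusted p = 0.751). DAF-16 targets had 9 higher and 6 lower of 21 (median 0.13, camera adjusted p = 0.101). The nuclear-encoded respiratory chain had 13 higher and 23 lower of 44 (median -0.27, camera adjusted p = 0.264). Mitochondrial ribosomal proteins had 30 higher and 22 lower of 67 (median 0.19, camera adjusted p = 0.857). Histones had 11 higher and 7 lower of 46 (median -0.02, camera adjusted p = 0.706, 11 higher and 6 lower adjusted over the list alone). Neurons had 7 higher and 4 lower of 20 (median 0.06, camera adjusted p = 0.615). Body wall muscle had 10 higher and 4 lower of 23 (median 0.16, camera adjusted p = 0.705). Pharynx had 3 higher and 7 lower of 14 (median -0.64, camera adjusted p = 0.325). Intestine had 4 higher and 6 lower of 20 (median -0.19, camera adjusted p = 0.455). Hypodermis and moulting had 8 higher and 11 lower of 33 (median -0.24, camera adjusted p = 0.633). Early embryo genes had 18 higher and 2 lower of 35 (median 0.67, camera adjusted p = 0.109, 15 higher and 2 lower adjusted over the list alone). Adjusted over the list alone, the counts were the same where none is given. With the length trend removed, the respiratory chain (adjusted p = 0.00216, lower), mitochondrial ribosomal proteins (0.00605, lower, with the direction turned) and body wall muscle (0.0368, higher) passed. Fatty acid synthesis passed, as lower, with only N2 replicates 3 and 4 as controls (0.0325) and without the labelled ΔIDR replicate 4 (0.0350). Endoplasmic reticulum stress genes passed, as lower, without N2 replicate 4 (0.0214) or the labelled ΔIDR replicate 3 (0.0179) or 4 (0.0408). The median of all genes moved by 0.36 when libraries were scaled by total counts, and the medians of autophagy, fatty acid oxidation, histones, hypodermis and moulting, intestine, lysosome and nuclear-encoded respiratory chain turned above 0. With the length trend removed the medians of autophagy, fatty acid oxidation, hypodermis and moulting and intestine turned above 0 and those of DAF-16 class I targets, cytosolic heat shock response and mitochondrial ribosomal proteins below 0, and with only N2 replicates 3 and 4 as controls those of autophagy, histones and hypodermis and moulting turned above 0.

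Of the 10576 genes called here, 9191 were also called with total counts, 9176 with only N2 replicates 3 and 4 as controls and 8164 with the length trend removed. The share of called genes that were higher was 52.2% with TMM and 66.7% with total counts.

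**Figure D4:**
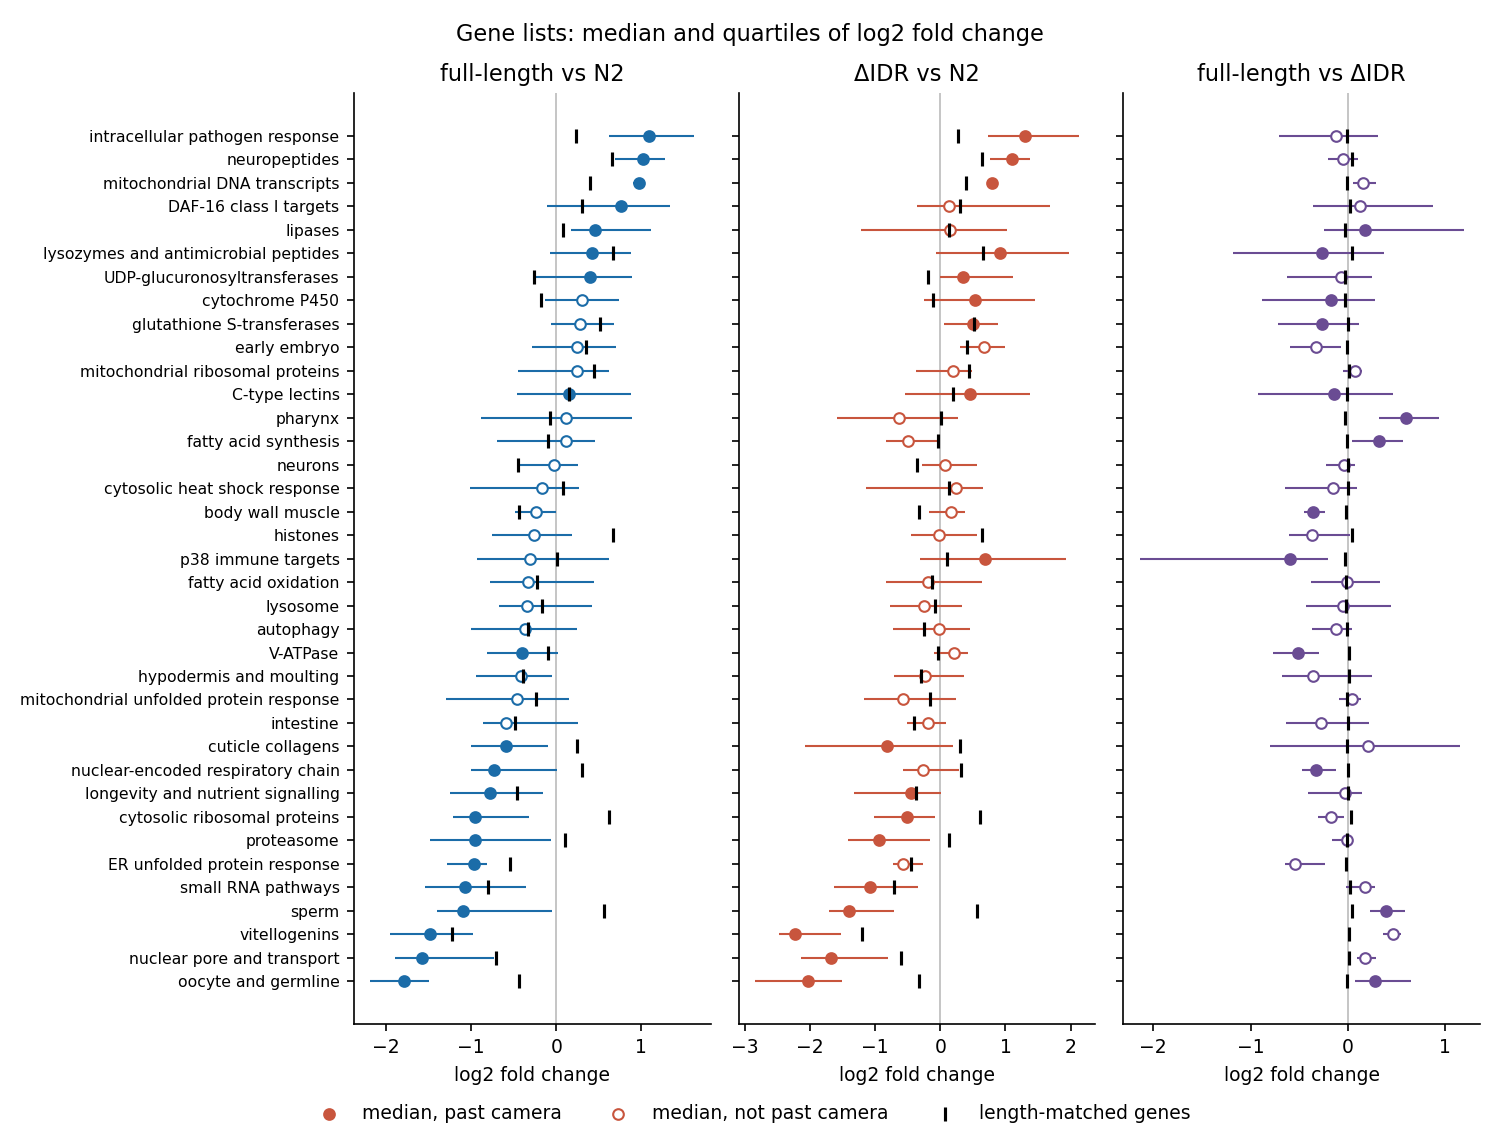
Median log2 fold change of the 37 gene lists (circles) with quartiles (lines) in the 3 comparisons of libraries as labelled; filled circles passed camera with its preset correlation, and black marks are medians of length-matched genes. Oocyte and germline genes lie at -1.78 and -2.03 against N2, and p38 immune targets at -0.60 between the lines. Scaled by total counts, the V-ATPase median of -0.40 against N2 turns to 0.05.

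Both lines shared much of their difference from N2. Of the tested genes, 3980 were higher and 4308 lower in both lines, where independent lists of the same sizes would share 1821 and 1801, and 263 were called in opposite directions. Across genes the fold changes correlated at r = 0.796, and 84.0% had the same sign. Simulated unchanged groups that share controls gave r = 0.672 and 76.1%. They may lack the shared spread of the real N2 libraries. The covariance was 0.984 against 0.0525 simulated, and r averaged 0.726 over the 6 ways to give each line its own 2 N2 libraries. With the length trend removed, which both lines share against N2, r was 0.743 and the covariance 0.703.

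The direct comparison of the lines asks which transcripts differ between the transgenes with and without the disordered region, and N2 enters it through the filter, the scaling and the pooled error. By camera, p38, lysozyme, lectin, proton pump, respiratory chain and muscle lists were lower in the labelled full-length than in the labelled ΔIDR libraries. Sperm, fatty acid synthesis and lipase lists were higher, with most members uncalled. With an estimated correlation 2 of the 13 lists passed, the p38 immune targets and the proton pump. The others had adjusted p from 0.208 to 0.886. The level of irg-5 was 10.1 ± 1.01 CPM in the labelled full-length libraries and 683 ± 38.2 CPM in the labelled ΔIDR libraries (SD, n = 4), and that of the proton pump gene vha-12 198 ± 3.50 CPM and 399 ± 20.97 CPM. The lysosomal lipase gene lipl-3 was at 5.98 ± 0.877 CPM and 0.202 ± 0.0385 CPM, and the nuclease gene nuc-1, whose product degrades DNA in lysosomes, at 132 ± 10.7 CPM and 31.7 ± 3.49 CPM. By edgeR's quasi-likelihood test 1256 genes were higher and 2480 lower, and 13 lists passed camera. The 1256 became 2304 with the 8 libraries alone, 2018 in DESeq2's test and 710 with the stricter filter. The share of called genes that were higher was 33.6% with TMM, 45.1% with DESeq2's size factors and 43.97% with total counts. It was 46.7% with the length trend removed, although the lines differed little in that trend, and 1256 became 831 or 803 without the labelled full-length replicate 3 or 4. Of the 3736 genes called, 3101 were also called with total counts and 3583 with the length trend removed.

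The p38 immune targets and the proton pump were the lists that passed camera with an estimated correlation as well. For p38 immune targets, 10 of 22 genes were lower, 3 were higher and 9 did not pass (14 and 3 adjusted over the list alone), with a median of -0.60 (adjusted p = 0.0351 with an estimated correlation). List members irg-5 at -6.09 (SE 0.201) and irg-4 at -3.06 (SE 0.122) were lower. Higher were dod-24 at 1.88 (SE 0.185) and irg-1 at 1.75 (SE 0.257). For the vacuolar proton pump, 15 of 21 genes were lower and 6 did not pass (16 lower and 1 higher adjusted over the list alone). Its median was -0.51 (adjusted p = 0.0241 with an estimated correlation), with vha-12 at -1.01 (SE 0.104) and vha-20 at -0.85 (SE 0.0883).

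Some other immune and detoxification lists were lower in the labelled full-length libraries. For lysozymes and antimicrobial peptides, 34 of 71 genes were lower, 13 were higher and 24 did not pass (35 and 16 adjusted over the list alone), with spp-12 at -5.54 (SE 0.231) and lys-6 at -2.34 (SE 0.127) and a median of -0.26 (adjusted p = 0.793 with an estimated correlation). The saposin-like gene spp-1 went the other way at 1.67 (SE 0.124). In the C-type lectin family, 36 of 106 genes were lower, 18 were higher and 52 did not pass (37 and 23 adjusted over the list alone), with clec-52 at -3.75 (SE 0.146), clec-13 at 0.285 ± 0.135 CPM against 26.99 ± 2.15 CPM, and a median of -0.14 (adjusted p = 0.401 with an estimated correlation). Of glutathione S-transferases, 15 of 42 genes were lower, 2 were higher and 25 did not pass (17 and 2 adjusted over the list alone), with gst-39 at -3.62 (SE 0.133) and a median of -0.26 (adjusted p = 0.838 with an estimated correlation). Of cytochrome P450 enzymes, 22 of 62 genes were lower, 9 were higher and 31 did not pass (24 and 11 adjusted over the list alone), with cyp-13A5 at -2.93 (SE 0.124), cyp-35A2 at 1.26 (SE 0.140) and a median of -0.17 (adjusted p = 0.234 with an estimated correlation). The P450 call ended with the length trend removed (adjusted p = 0.0544) and without the labelled ΔIDR replicate 4 (0.0614).

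The body wall muscle and respiratory chain lists were lower as well. In body wall muscle, 15 of 23 genes were lower, 1 was higher and 7 did not pass (16 and 1 adjusted over the list alone), with the troponin T gene tnt-3 at -1.18 (SE 0.0990), unc-98 at -0.92 (SE 0.119) and a median of -0.36 (adjusted p = 0.879 with an estimated correlation). For the nuclear-encoded respiratory chain, 21 of 44 genes were lower and 23 did not pass (23 adjusted over the list alone), with the complex III gene ucr-2.1 at -0.93 (SE 0.115), the ATP synthase gene asb-2 at -0.83 (SE 0.105) and a median of -0.33 (adjusted p = 0.793 with an estimated correlation).

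Lipase, fatty acid synthesis, pharynx and sperm lists were instead higher. For fatty acid synthesis, 10 of 24 genes were higher, 1 was lower and 13 did not pass (10 and 1 adjusted over the list alone), with the desaturase gene fat-2 at 0.86 (SE 0.0975), the elongase gene elo-6 at 0.97 (SE 0.152) and a median of 0.32 (adjusted p = 0.246 with an estimated correlation). For lipases, 7 of 20 genes were higher, 2 were lower and 11 did not pass (8 and 2 adjusted over the list alone), with lipl-3 at 4.84 (SE 0.252), lipl-1 at 2.99 (SE 0.447), lips-15 at 1.99 (SE 0.141), lips-10 at -1.52 (SE 0.146) and a median of 0.17 (adjusted p = 0.208 with an estimated correlation). The lipl-1 difference was 3.92 without the labelled ΔIDR replicate 4. In the pharynx, 6 of 14 genes were higher and 8 did not pass (7 higher and 1 lower adjusted over the list alone), with the myosin gene myo-2 at 1.17 (SE 0.270), the gland gene phat-6 at 0.76 (SE 0.142) and a median of 0.60 (adjusted p = 0.776 with an estimated correlation). For sperm, 20 of 70 genes were higher and 50 did not pass (21 higher and 1 lower adjusted over the list alone), with spe-4 at 1.39 (SE 0.264) and a median of 0.40 (adjusted p = 0.886 with an estimated correlation). Oocyte and germline genes passed camera as higher with a median of 0.28 (adjusted p = 0.886 with an estimated correlation), yet glh-1 at 0.50 (SE 0.156, edgeR adjusted p = 0.0297), puf-6 at 0.87 (SE 0.306, edgeR adjusted p = 0.0492) and perm-2 at -0.42 (SE 0.140, edgeR adjusted p = 0.0390) were the only members called of 38. Once the length trend was removed, 18 of the 38 were called, all higher, with a median of 0.32 and camera adjusted p = 0.00177. None of these 3 calls held in every fit that left out a library: the adjusted p reached 0.0798 for glh-1, 0.127 for puf-6 and 0.102 for perm-2. Adjusted over the list alone none was called by edgeR, and fry, which tests a list on its own, did not pass this list or sperm (adjusted p = 0.271 and 0.0639).

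Outside these lists pacs-1, among the genes with the largest increases, was at 2.39 (SE 0.105). Of the regulators named in advance, sqst-1 was lower at -0.98 (SE 0.123, edgeR adjusted p = 2.62e-05) and lmp-1 at -0.58 (SE 0.146, edgeR adjusted p = 0.00802). The hlh-30 difference of -0.41 (SE 0.141, edgeR adjusted p = 0.0454) did not pass with DESeq2's size factors (adjusted p = 0.104), in DESeq2's own test (0.0922), with the replicate number as a block (-0.41, adjusted p = 0.0625), or when any 1 of the 8 libraries was left out (0.0565 to 0.107). Values for lgg-1 and fat-7 were -0.12 (SE 0.109, edgeR adjusted p = 0.435) and 0.42 (SE 0.256, edgeR adjusted p = 0.256), and without the labelled ΔIDR replicate 4 fat-7 passed (0.74, adjusted p = 0.0334). The lysosome list had 15 higher and 15 lower of 56 (median -0.05, camera adjusted p = 0.546, 15 higher and 16 lower adjusted over the list alone). The autophagy list had 4 lower of 26 (median -0.12, camera adjusted p = 0.372), and neither passed. Lysosome genes with the smallest adjusted p were nuc-1 at 2.06 (SE 0.106) and the thioesterase gene ppt-1 at -2.64 (SE 0.171).

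The remaining lists did not pass camera. Nuclear pore and transport had 1 higher of 39 (median 0.18, camera adjusted p = 0.0988). Endoplasmic reticulum stress genes had 10 lower of 18 (median -0.54, camera adjusted p = 0.0988, 12 lower adjusted over the list alone). Collagens had 21 higher and 40 lower of 127 (median 0.21, camera adjusted p = 0.102, 30 higher and 42 lower adjusted over the list alone). Vitellogenins had 1 higher of 6 (median 0.47, camera adjusted p = 0.103). Cytosolic ribosomal proteins had 17 lower of 82 (median -0.18, camera adjusted p = 0.132, 15 lower adjusted over the list alone). Mitochondrial DNA genes had 2 higher of 12 (median 0.15, camera adjusted p = 0.132). Histones had 11 lower of 46 (median -0.36, camera adjusted p = 0.218). Small RNA pathways had 1 higher and 3 lower of 47 (median 0.17, camera adjusted p = 0.227). Hypodermis and moulting had 3 higher and 10 lower of 33 (median -0.36, camera adjusted p = 0.228, 4 higher and 11 lower adjusted over the list alone). The intracellular pathogen response had 5 higher and 9 lower of 28 (median -0.12, camera adjusted p = 0.228, 6 higher and 10 lower adjusted over the list alone). Mitochondrial ribosomal proteins had 1 higher and 2 lower of 67 (median 0.07, camera adjusted p = 0.280). Cytosolic chaperones had 6 lower of 20 (median -0.15, camera adjusted p = 0.292). Early embryo genes had 1 higher and 5 lower of 35 (median -0.33, camera adjusted p = 0.372). Neurons had 4 lower of 20 (median -0.04, camera adjusted p = 0.523). DAF-16 targets had 6 higher and 5 lower of 21 (median 0.13, camera adjusted p = 0.546, 7 higher and 5 lower adjusted over the list alone). Fatty acid oxidation had 7 higher and 12 lower of 43 (median -0.01, camera adjusted p = 0.581, 9 higher and 14 lower adjusted over the list alone). Glucuronosyltransferases had 11 higher and 18 lower of 58 (median -0.07, camera adjusted p = 0.616, 12 higher and 20 lower adjusted over the list alone). Intestine had 4 higher and 7 lower of 20 (median -0.28, camera adjusted p = 0.684, 4 higher and 8 lower adjusted over the list alone). Longevity and nutrient signalling had 8 lower of 34 (median -0.03, camera adjusted p = 0.684). The proteasome had 1 higher and 1 lower of 33 (median -0.01, camera adjusted p = 0.746). Mitochondrial stress genes had 1 higher and 1 lower of 12 (median 0.05, camera adjusted p = 0.861). Neuropeptides had 3 higher and 7 lower of 117 (median -0.05, camera adjusted p = 0.861, 3 higher and 6 lower adjusted over the list alone). Collagens had a median above 0 while camera's direction was lower. Several of these lists passed in some alternatives, fry aside: endoplasmic reticulum stress genes, as lower, in 4 (adjusted p from 0.0238 to 0.0413), and nuclear pore genes in 3 (0.0165 to 0.0376) and vitellogenins in 3 (0.0217 to 0.0313), as higher. Collagens passed without the labelled full-length replicate 3 (0.0329) or the labelled ΔIDR replicate 1 (0.0468), mitochondrial DNA genes without the labelled ΔIDR replicate 1 (0.0381), and cytosolic ribosomal proteins without the labelled ΔIDR replicate 3 (0.0231). With another scaling or the length trend removed, the medians of UDP-glucuronosyltransferases, fatty acid oxidation, longevity and nutrient signalling, lysosome, neurons, neuropeptides and proteasome turned above 0 and none of the other medians near 0 fell below it.

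**Figure D5:**
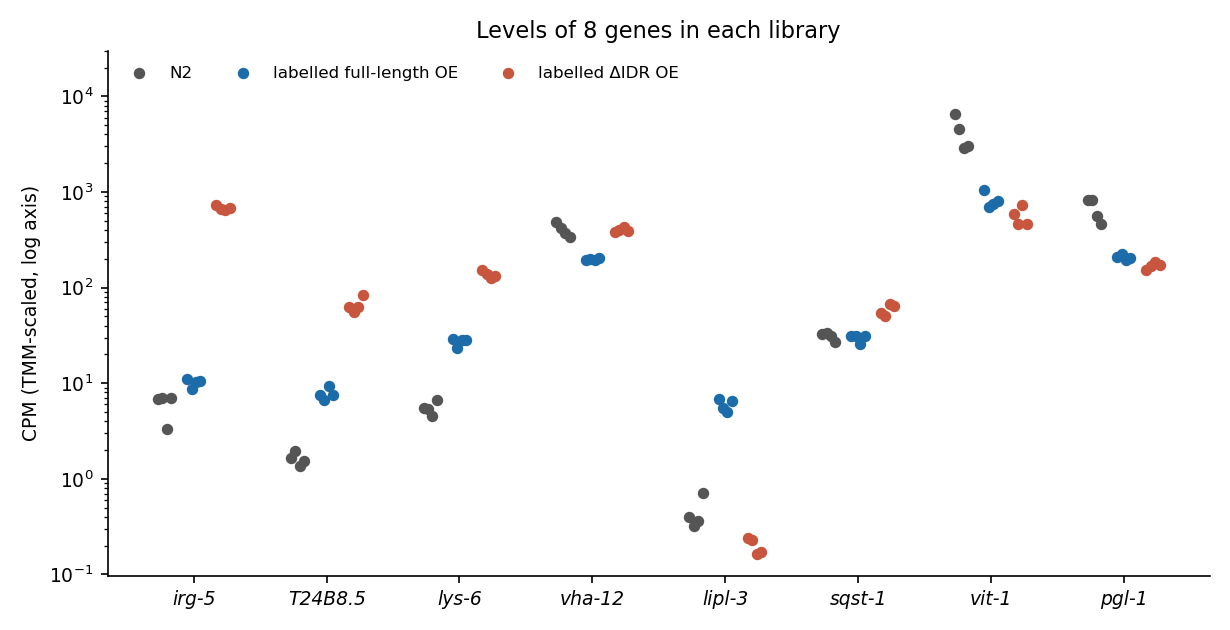
Levels of 8 genes in each library, in CPM on a log axis, for N2 and the 2 lines labelled as overexpressing (OE); each point is a library. The immune genes irg-5, T24B8.5 and lys-6 are highest in the labelled ΔIDR libraries, lipl-3 is highest in the labelled full-length libraries, and vit-1 and pgl-1 are highest in N2.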

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

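The tests of exchanged labels and of less germline RNA for npp-16, of fewer germline transcripts as the source of the length trend, of less germline RNA for the germline list, and of scaling and of a lower share of germline RNA for the p38 targets were chosen only after the results were seen. The p38 scaling test replaced an earlier camera test, which a factor common to all genes hardly changes. The patterns were also regrouped after their results were known, and the length measurements were added after the data were seen.

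In both lines labelled as overexpressing, npp-16 was lower than in N2. Gene length is argued against as the whole reason, since npp-16 stayed at -1.003 and -1.52 with the length trend removed (-0.69 and -1.14 with only N2 replicates 3 and 4 as controls). Exchanged labels of N2 and the full-length line cannot be told apart from the rest (percentile 59.0 of the nuclear pore list). That labelled ΔIDR libraries (at most 40.1 CPM) lay below labelled full-length ones (at least 46.1 CPM) cannot decide it, with transgene counts unknown. Less germline RNA per animal may account for the decrease, as npp-16 moved with its list and lay at percentile 48.7 of it in the labelled ΔIDR line. That the transgene RNA adds little to these counts, through its sequence or a low level, stays open and was not tested.

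Oocyte and germline genes were lower, and long transcripts were lower, in both lines than in N2. TMM scaling alone is argued against, as the germline medians were -1.28 and -1.62 with total counts, and so is length alone, as they were -1.30 and -1.59 with the trend removed. Fewer germline transcripts alone would not produce the length trend within ribosomal protein genes, where rho was -0.570 and -0.560. Less germline RNA per animal at collection cannot be told apart from lower expression in the germline: with the length trend removed, the axis along which N2 libraries differ correlated with the fold changes at r = 0.506 and 0.358, but the germline list set its direction, it was not set against a null, and sperm genes, lower in both lines, had a median of 0.0454 along it. Whether RNA quality, library making or the strains' own RNA sets the length trend stays open.

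The p38 immune targets were higher in the labelled ΔIDR libraries than in the labelled full-length libraries, with medians of 0.69 and -0.31 against N2 (the latter above 0 with total counts), a difference of -0.997 (labelled full-length minus labelled ΔIDR). Scaling was hardly tested: total counts and DESeq2's size factors moved all genes by 0.08 and 0.07 between the lines (list median -0.52 and -0.53). A single library is argued against by an adjusted p of at most 1.78e-07 in 8 leave-outs. A lower share of germline RNA as the whole source would move all somatic genes alike. It is argued against only for the 45.5% of these targets that lay more than 3 SE below the median of 5 somatic tissue lists, itself -0.22. The gene calls already known made such a share likely, and it was not compared with that of other genes. Less germline RNA at collection in other ways cannot be told apart from a difference between the strains: the N2 axis correlated at r = -0.253 with the change from labelled full-length to labelled ΔIDR across 199 immune genes, where a positive value was predicted, but sperm genes rise along that axis (median 0.28), so it does not measure germline RNA alone. Insertion site, background mutations and differences in culture stay open and untested.

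Other lists and genes had values of opposite sign against N2 in the lines. As differences of the medians, labelled full-length minus labelled ΔIDR, V-ATPase genes gave -0.60 (-0.40 and 0.21), fatty acid synthesis 0.60 (0.11 and -0.49), body wall muscle -0.40 (-0.24 and 0.16) and pharynx 0.75 (0.11 and -0.64). Between the lines these passed camera (adjusted p 0.0241, 0.246, 0.879 and 0.776 with an estimated correlation). Against N2 most did not pass camera: adjusted p was 0.0420 and 0.431 for V-ATPase, 0.854 and 0.0652 for fatty acid synthesis, 0.183 and 0.705 for body wall muscle, and 0.748 and 0.325 for pharynx. With total counts the V-ATPase and body wall muscle medians of the labelled full-length libraries turned above 0. As log2 fold changes, lipl-1 differed by 2.99 (1.08 and -1.91, 3.92 without the labelled ΔIDR replicate 4), lipl-3 by 4.84 (3.68 and -1.16) and sqst-1 by -0.98 (-0.05 and 0.92). These 3 passed edgeR's test between the lines. Few lipl-1 and lipl-3 counts leave their labelled ΔIDR sign uncertain. Against N2, labelled full-length sqst-1 did not pass (adjusted p = 0.721) and its sign turned in some fits.

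Some libraries stood apart from the other 3 of their group by Dixon's test, which picks about 1 in 20 groups by chance; 255 groups were checked. N2 replicate 1 had the highest total count (24.6 M estimated counts, others 20.8 to 21.4), the lowest fat-7 (39.4 CPM, others 65.9 to 71.2), the highest mean log2 CPM of p38 targets (3.45, others 3.23 to 3.27) and the lowest of mitochondrial ribosomal proteins (6.05, others 6.23 to 6.25). N2 replicate 3 was lowest in irg-5 (3.29 CPM, others 6.84 to 7.08). N2 replicate 4 was highest in mean log2 CPM of mitochondrial DNA genes (9.05, others 8.58 to 8.65) and lowest in histones (1.81, others 2.13 to 2.16). The labelled full-length replicate 1 was highest in fatty acid synthesis (6.39, others 6.27 to 6.28) and the mitochondrial unfolded protein response (6.40, others 6.35 to 6.36), and replicate 3 lowest in sqst-1 (25.8 CPM, others 31.4 to 31.5). The labelled ΔIDR replicate 3 was highest in lin-41 (39.5 CPM, others 20.1 to 21.7), cbd-1 (326 CPM, others 190.1 to 195), rme-2 (130.6 CPM, others 78.8 to 86.8), F11D11.3 (22.4 CPM, others 19.6 to 20.0) and mean log2 CPM of the V-ATPase list (8.28, others 8.202 to 8.21). The labelled ΔIDR replicate 4 was highest in lipl-1 (1.85 CPM, others 0.278 to 0.442).

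All 35 splits of the 8 libraries of a comparison into groups of 4 were also run. The real split called 10084, 10576 and 3736 genes, as many in 1, 1 and 1 of the 35 splits, so chance is excluded for these counts. The highest other splits called 2625, 2392 and 0 genes by edgeR's quasi-likelihood test; for the comparison of the lines, up to 1701 genes had an unadjusted p under 0.05 in another split, against 5335 in the real one, and no other tool was run on the splits. For lists past camera, the real 20, 18 and 13 were reached in 5, 3 and 11 splits, which does not argue against chance. The highest others were 21, 19 and 18.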

How the results depend on the processing

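Scaling by total counts, voom, length-scaled counts, N2 replicates 3 and 4 as the only controls and removal of the length trend were chosen only after the data were seen. For the genes named, 2232 of 2293 recomputed values kept their direction and side of the threshold, 40 no longer passed, 4 newly passed and 17 turned their sign. Over the 37 lists, 1487 of 1628 did, 85 no longer passed, 54 newly passed and 2 turned. Fewer genes pass by construction with a log2 fold change above 1: 1753 higher and 2922 lower in the labelled full-length libraries against N2, 2274 and 2958 in the labelled ΔIDR libraries, and 514 and 870 between the lines. With camera's estimated correlation, which allows for genes that move together, 0, 0 and 2 lists passed, where 3, 4 and 5 had an unadjusted p under 0.05 and fry, which does not compare a list with other genes, passed 29, 27 and 19.

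Between the lines the number of higher genes was 2018 in DESeq2's test, 710 with the stricter filter, which tests fewer genes, 2304 with the 8 libraries alone, 1904 with voom and 2260 with the length trend removed. There npp-16 kept 0.45 and passed with the 8 libraries alone (adjusted p = 0.000696), without N2's wider spread. Else it passed only with total counts (0.53, 0.0218), voom (0.45, 0.0329) and the length trend removed (0.52, 0.0375). No cause was tested. With split N2 libraries the correlation of the lines' effects averaged 0.726.

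Leaving out 1 library gave 4438 to 4970 higher and 5017 to 5288 lower genes for the labelled full-length libraries against N2, 5105 to 5561 and 4811 to 5084 for the labelled ΔIDR libraries, and 803 to 1203 and 2038 to 2357 between the lines. Lists past camera ran from 18 to 21, 16 to 20 and 12 to 16. The npp-16 difference ran from -1.47 to -1.09, -1.92 to -1.54 and 0.40 to 0.49.

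The cause of the turns of sign was not tested. For sqst-1 in the labelled full-length libraries against N2 the values were 0.0354 with the stricter filter, 0.40 with total counts, 0.68 with the length trend removed and 0.0376 with only N2 replicates 3 and 4. Leaving out a library gave -0.11 (without N2 replicate 4) to 0.0143 (without the labelled full-length replicate 3). For hlh-30 they were 0.0012 with total counts and 0.33 with the length trend removed. In the labelled ΔIDR libraries against N2, hlh-30 was 0.0285 with the stricter filter, 0.33 with total counts, 0.70 with the length trend removed and 0.24 with only N2 replicates 3 and 4. Leave-outs gave -0.16 (without N2 replicate 3) to 0.0671 (without N2 replicate 1). There lmp-1 was 0.19 with total counts and 0.13 with only N2 replicates 3 and 4, and fat-7 was 0.23 with total counts and -0.42 to 0.0194 when a library was left out (without the labelled ΔIDR replicates 4 and 1; 0.0146 without replicate 2). Mitochondrial ribosomal proteins turned to lower with the length trend removed (camera adjusted p = 0.0330 and 0.00605).

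Same-numbered libraries share only a number: 2 of 12 pairs correlated above 0.1, and 4 libraries correlated best with their own number. The fit with the replicate number as a block called 4786 higher and 5178 lower, 5369 and 4995, and 1197 and 2353 genes, and 9828, 10260 and 3406 of the main calls were kept. With that block, 19, 17 and 13 lists passed, the V-ATPase list in the labelled full-length libraries (adjusted p = 0.0641) and the longevity list in the labelled ΔIDR libraries (0.0550) did not pass, and hlh-30 between the lines did not (0.0625); no other call of a named gene or list changed.

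With few genes changed, the simulated test recovered 23.4% of 1.5-fold changes, which need not hold here. Small differences not called can be real. The more spread N2 libraries enter the pooled error of the comparison of the lines.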

Other observations

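The families of genes sharing a symbol prefix, the comparison of neuropeptide genes with other lists and the medians along the N2 axis were chosen only after the results were seen.

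Families outside the fixed lists also differed. Among 101 families of at least 10 tested genes, the F-box family fbxa had 112 higher and 1 lower of 145 in the labelled full-length libraries against N2 (median 1.05, 0.83 with the length trend removed). In the labelled ΔIDR libraries it had 115 higher and 2 lower (median 0.99). Genes of the related family math, with a MATH domain, were higher in 20 and lower in 2 of 23 cases in the labelled full-length libraries. The 17 nspc genes were higher in both lines (medians 1.38 and 1.47). Nuclear hormone receptor genes (nhr) had 77 higher and 30 lower of 189 in the labelled full-length libraries, and 114 and 22 in the labelled ΔIDR libraries. These families passed camera with its preset correlation in the comparisons given, and passed with the length trend removed. With an estimated correlation the adjusted p was 0.556 for fbxa and 0.721 for math, nspc and nhr in the labelled full-length libraries, and 0.626 for fbxa, nspc and nhr in the labelled ΔIDR libraries.

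Between the lines, 28 of 75 genes of the F-box family fbxb were lower in the labelled full-length libraries (median -0.61), as were 7 of 12 bZIP factor genes (zip, median -0.70) and 8 of 12 galectin genes (lec, median -0.47). They passed camera with its preset correlation, and with an estimated correlation their adjusted p was 0.994, 0.923 and 0.923.

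The median of neuropeptide genes exceeded that of pan-neuronal genes by 1.05 in the labelled full-length libraries and 1.03 in the labelled ΔIDR libraries, and that of body wall muscle genes by 1.26 and 0.93. These lists differ in transcript length, and the differences go largely with it. After removal of the length trend the medians were 0.49 and 0.57 for neuropeptides, 0.46 and 0.42 for neurons, and 0.01 and 0.42 for body wall muscle. Along the main axis on which the N2 libraries differ, from replicate 1 to replicate 4 and holding 63.6% of the N2 variance, neuropeptide genes had a median change of 0.52, body wall muscle genes 0.24 and pan-neuronal genes 0.01. On that axis oocyte and germline genes had -1.29, nuclear pore genes -1.19, vitellogenins -1.12 and sperm genes 0.28.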
